A study of Mus musculus with 6 samples.

How the data were processed

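Total liver RNA of 6 male C57BL/6 mice aged 8 weeks was measured, 3 wild type (WT) and 3 with the Hmgb2 gene knocked out (HMGB2-KO). Each liver was hybridised to 1 Clariom S mouse array, a single-colour Affymetrix array that reads each gene through several short probes, after Trizol extraction and biotin labelling of cDNA, per the labels' protocols. The labels name no treatment or surgery for these livers, and they give each animal a number but no litter, day or batch. One column of values per liver was used, and 0 columns were left unused.

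The deposited table holds 22206 rows of values on a log scale, taken here as log2, from -8.60 to 6.93. Each row is given relative to a baseline of its own. The base of the logarithm, the summarization of probes, the normalization between arrays and the baseline are not given in the sources used here. The row median over the 6 livers is 0 in 8.33% of rows, so the baseline was not the median of these 6 arrays. The gene Kif11 lies below its baseline in all 6 livers, from -2.27 to -1.00 after the centring described below. A mean or median over any of these arrays alone could not give that. A value is thus a difference from an unknown reference level, differences between livers can be read, and no gene's absolute level or level against another gene can be. With 3 arrays per group, the number of arrays limits the precision.

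Rows were named through the platform annotation, which pairs 19572 rows with 1 gene symbol each, 0 rows with several and leaves 2634 rows unnamed here. All 19572 gene identifiers matched the RefSeq gene table of assembly GRCm38.p6, with the same symbol. That table was used for names and for which genes neighbour each other. The array table names no genome build, so no coordinates are given. For the 55 genes with several rows, the row with the highest mean over the 6 livers was kept, which left 19505 genes. Because the values are differences from a baseline, that rule does not pick the brightest row, and the mean of the rows was tried as well.

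The column medians differed by more than 0.1 log2. The plan made before the data were examined called for quantile normalization in that case. Quantile normalization acts on ranks within an array, and ranks of differences from row baselines are not ranks of level. The main setting therefore centred each array on its median, which was decided after the values were seen and before any test was run. Quantile normalization and the values as deposited were kept as alternatives. Against centring, quantile normalization moved the log2 fold change of 88 genes by over 0.5, and 49 of these were among the 187 genes whose mean over the livers lies more than 1 log2 from the baseline. The values as deposited lower every log2 fold change by 0.12 and put the median of all genes at -0.12, against -0.00 after centring.

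Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, genotype as the 1 factor), with Benjamini-Hochberg adjustment over the 19505 genes and a threshold of 0.05. A looser count took genes with a fold change of at least 1.5 and an unadjusted p under 0.05. Fixed gene lists, 36 in all, were tested with limma's camera at a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The same lists were tested with an estimated correlation, and with fry, which tests a list against no change rather than against the other genes. The lists hold 1042 entries, of which 925 were measured, and Hmgb2 is in none of them. Genes around Hmgb2 were compared, by their mean absolute moderated statistic, with 100000 random windows of as many measured neighbouring genes (a permutation test). The plan asked for windows matched on expression, which these values do not give. Lists, tests and the rule for named genes were fixed before the data were examined.

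The rule names Hmgb2, then up to 12 genes per direction with the largest fold change among genes past the adjusted threshold whose 3 HMGB2-KO values lie on 1 side of all 3 WT values. Open places are filled by genes with at least 1.5-fold change, unadjusted p under 0.05 and no overlap of the groups. Predicted genes, olfactory and vomeronasal receptors, small RNAs and receptor segments take no place. For each shifted list, and for the lists of cell cycle, growth signalling, lipogenesis, cholesterol and hepatocyte identity genes, the 4 members with the smallest p are named, and Hmgb1 and Hmgb3 are named always.

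The statistics were tested on simulated data for the comparison of HMGB2-KO with WT, with 19505 genes, the real spread and 3 livers per group. In each of 20 runs 200 genes were changed, 100 of them 2-fold and 100 of them 4-fold. At the adjusted threshold 59.1% of the former and 91.5% of the latter were found, and 4.11% of calls were false. The adjusted threshold eases as more genes change, so these shares do not carry over to a comparison with few changed genes. Simulated genes were independent, and under that condition 60 of 60 lists shifted by 0.3 log2 and 1 of 720 unshifted lists were called.

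Quantile normalization was the setting the plan called for here, and it became an alternative when centring replaced it. Other alternatives were fixed before the data were examined. They were the values as deposited, a variance trend with robust priors, array weights and the mean of the rows. The replicate number as a block, each liver left out in turn and a per-gene test without moderation were also among them. So were an adjusted threshold of 0.1 and a 2-fold threshold. The last were list tests with an estimated correlation, on ranks and with fry, and windows of 10 and 40 genes on each side of Hmgb2. Filters on dim rows were also planned and were not run, since the values hold no level. Alternatives chosen after seeing the data set aside values more than 2 log2 below each of the other 5 arrays, used the animal numbers as a term, or kept only animals 38 to 41. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.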

Results

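Liver transcripts of WT and HMGB2-KO mice were compared to find genes whose expression goes with that of Hmgb2, which encodes an abundant DNA-bending chromatin protein with HMG boxes. The data are 6 arrays, 1 per liver, with 3 livers of each genotype. The study as a whole concerns HMGB2 in liver regeneration and hepatocyte size. All values below are log2 differences from a row baseline after each array was centred on its median, and fold changes are HMGB2-KO against WT. The livers carry separate animal numbers in the labels, 38, 40 and 31 for WT replicates 1 to 3 and 39, 41 and 32 for HMGB2-KO replicates 1 to 3.

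The array of WT replicate 2 stood apart before centring. Its median over all rows was 0.26, against -0.05 to 0.01 on the other 5 arrays. Its 1091 rows of olfactory receptors, which liver hardly expresses, had a median of 0.51 against -0.12 to 0.02, and its 323 rows of vomeronasal receptors had a median of 0.63 against -0.11 to -0.00. The 19 rows of plasma proteins, which hepatocytes express strongly, had a median of 0.04 on that array and between -0.01 and 0.03 on the others. It also held 132 rows lying more than 2 log2 below each of the other arrays, against 33 in WT replicate 1 and 4 to 6 in the other 4 livers. One of them was Apoa2, a major apolipoprotein of the liver.

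**Figure D1:**
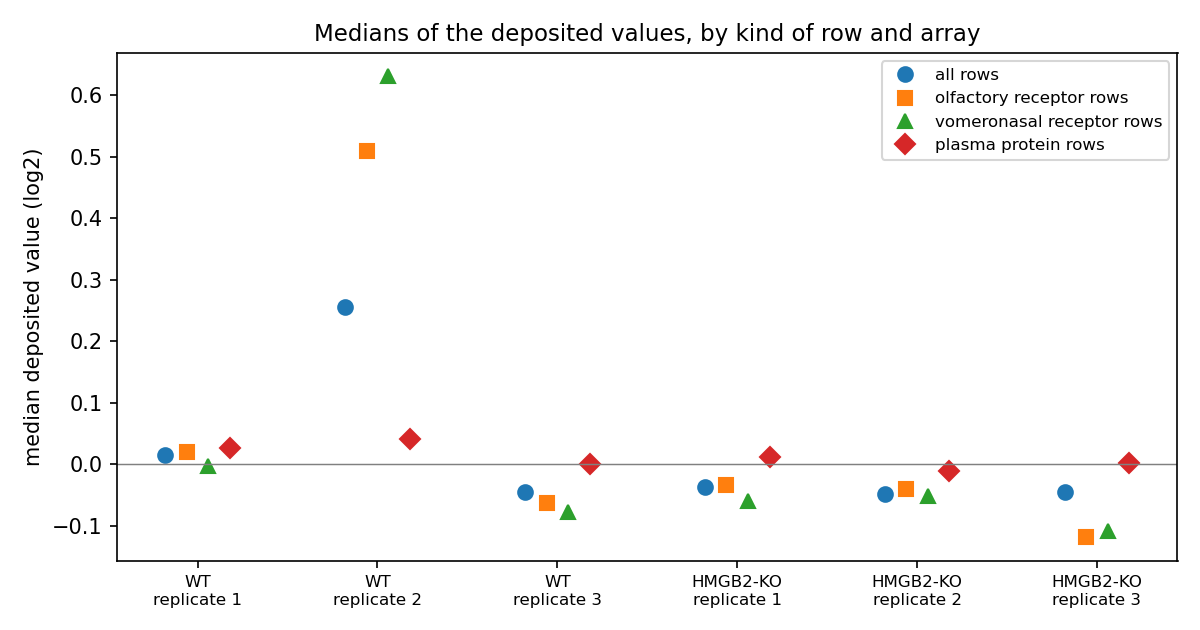
Median of the deposited log2 values (vertical axis) of all rows, olfactory receptor rows, vomeronasal receptor rows and plasma protein rows on each of the 6 arrays (horizontal axis). On the array of WT replicate 2 the medians of all rows and of both receptor families are 0.26, 0.51 and 0.63, while its plasma protein median of 0.04 lies near those of the other arrays.

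Hmgb2 itself was lower in the HMGB2-KO livers. Its value was 0.42 ± 0.05 in WT and -0.47 ± 0.17 in HMGB2-KO (SD, n = 3 each), a log2 fold change of -0.89 with a standard error of 0.13 and a 95% confidence interval of -1.20 to -0.58. That is 1.85-fold lower. The lowest WT liver was at 0.36 and the highest HMGB2-KO liver at -0.33, so every liver lay on the side its label gives. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 livers allow. In limma the adjusted p over all genes was 0.645, and Hmgb2 ranked 5 by p among the 19505 genes. Which part of the gene was deleted, and whether the probes lie in it, is not given in the sources used here. The paralogs did not pass the test, with Hmgb1 at 0.10 (SE 0.12), or -0.02 with the values as deposited, and Hmgb3 at -0.06 (SE 0.13).

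Across all genes, none passed the adjusted threshold. Among the genes named by rule as lower in HMGB2-KO were the cytochrome P450 genes Cyp2c40 (log2 fold change -1.40, SE 0.22), Cyp2c68 (-1.05, SE 0.21), Cyp2c69 (-1.05, SE 0.21) and Cyp2c67 (-0.99, SE 0.17). These genes are close copies of one another, so their single values are uncertain. Cyp2c40 was at 1.20 ± 0.19 in WT and -0.20 ± 0.41 in HMGB2-KO (SD, n = 3 each). Among those named as higher was the carboxylesterase Ces2b, at 0.55 ± 0.26 in WT and 2.28 ± 0.82 in HMGB2-KO, a log2 fold change of 1.73 (SE 0.38). The neighbouring family members Ces2a (0.11, SE 0.21) and Ces2e (0.08, SE 0.14), looked up after the values were seen, lay within their error of 0, on its lower side with the values as deposited.

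The smallest adjusted p in limma was 0.350, 717 genes had an unadjusted p under 0.05 where 975 would by chance, and 0 genes passed an adjusted threshold of 0.1. The per-gene test without moderation also gave 0 after adjustment, and 837 before it. At 1.5-fold and unadjusted p 0.05, 148 genes were counted, 11 higher and 137 lower in HMGB2-KO, of which 55 lower genes and 1 higher gene were olfactory or vomeronasal receptors. The share of lower genes was 92.6%, and 62.0% of 158 genes without WT replicate 2. The count was above 1.5 times this value without WT replicate 1 (274), WT replicate 3 (331), HMGB2-KO replicate 1 (225) or HMGB2-KO replicate 3 (237), and with the values as deposited (290, 98.3% lower).

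By the naming rule, 7 genes were available for the higher side, none past the adjusted threshold. After Ces2b these were Gpr1, a chemerin receptor (1.33, SE 0.45), Rnase13 (0.68, SE 0.18), Tnfrsf1b, a receptor for tumour necrosis factor (0.68, SE 0.25), Zfp280d (0.67, SE 0.14), Dio1, the deiodinase that makes active thyroid hormone in liver (0.62, SE 0.19), and Uri1 (0.62, SE 0.19). On the lower side, besides the 4 Cyp2c genes, stood Speer2 (-1.57, SE 0.29), Aadacl2fm1 (-1.50, SE 0.29), Esp4 (-1.31, SE 0.44, or -0.73 without HMGB2-KO replicate 2), Oog3 (-1.29, SE 0.28), Spag17 (-1.26, SE 0.30), Nrk (-1.16, SE 0.20), the interferon gene Ifna4 (-1.15, SE 0.30) and Ccdc169 (-0.99, SE 0.30). All of these keep their direction with the values as deposited and with quantile normalization. They keep it without WT replicate 2 too, but there Gpr1 was at 0.94, Spag17 at -0.88, Ifna4 at -0.81 and Ccdc169 at -0.73. Speer2, Aadacl2fm1, Oog3, Nrk, Rnase13, Dio1, Cyp2c68 and Cyp2c69 were also smaller in size there. Ces2b, Tnfrsf1b, Zfp280d, Uri1, Esp4, Cyp2c40 and Cyp2c67 were larger. For Speer2 (0.97), Aadacl2fm1 (1.27), Oog3 (1.26) and Spag17 (0.84) the highest value of all livers was that of WT replicate 2. So it was for Nrk (0.46), Ifna4 (1.03) and Ccdc169 (1.15), but not for Esp4 (0.16). Whether these genes are read above background in liver is unknown, since the values hold no level. They may thus not be liver transcripts lowered in HMGB2-KO. Of 80 genes followed with 1 liver left out, those named from the lists below among them, 36 changed by a factor over 1.5 either way. Of these, 2 changed sign.

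**Figure D2:**
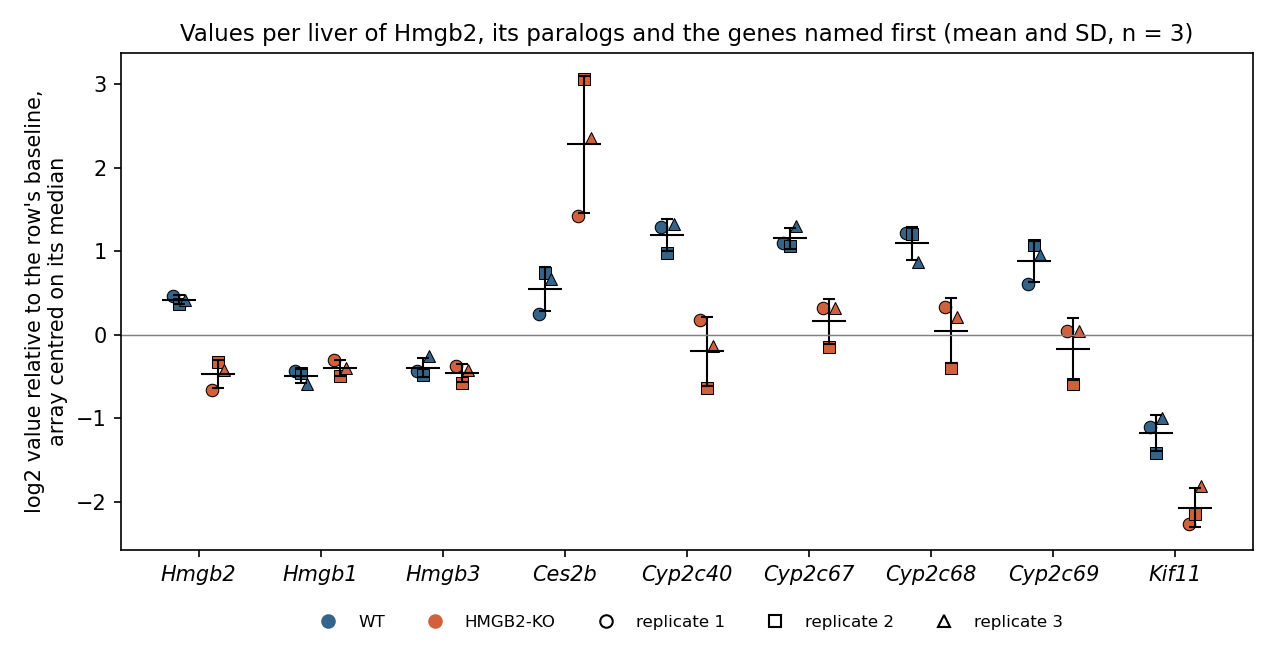
Log2 value relative to the row baseline after centring (vertical axis) of Hmgb2, Hmgb1, Hmgb3, Ces2b, the 4 Cyp2c genes and Kif11 in each liver, with colour for genotype, symbol for replicate, and bars for the mean and SD (n = 3). For Hmgb2, Ces2b, each of the 4 Cyp2c genes and Kif11 the 3 livers of a genotype lie on 1 side of the other 3, and Hmgb1 and Hmgb3 overlap. Ces2b and the Cyp2c genes were named by a rule that asks for this. Over all genes 9.67% have no overlap, where 10% would by chance.

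Of the 36 gene lists, 10 passed camera's adjusted threshold at the preset correlation, 8 higher and 2 lower in HMGB2-KO, and their medians were small. With an estimated correlation 0 passed (smallest adjusted p 0.595), and with fry, which asks whether a list differs from no change rather than from the other genes, 0 (0.360). Markers of Kupffer cells and other macrophages rose, with 17 of 20 genes higher and a median log2 fold change of 0.21 (adjusted p = 0.000853). By liver, the list's median was 0.24, 0.28 and 0.38 in WT replicates 1 to 3 and 0.45, 0.26 and 0.55 in HMGB2-KO replicates 1 to 3. The genotypes thus overlap. Among its genes Mpeg1 was at 0.39 (SE 0.17, or 0.25 without WT replicate 1) and the complement gene C1qa at 0.25 (SE 0.13). The complement gene C1qc was at 0.29 (SE 0.15, or 0.17 without WT replicate 2). The chemokine receptor Ccr2 was at 0.26 (SE 0.15, or 0.15 without HMGB2-KO replicate 1). Cholangiocyte markers fell, with 11 of 15 genes lower and a median of -0.22 (adjusted p = 0.0358), including the collagen receptor Ddr1 at -0.60 (SE 0.18), the mucin Muc1 at -0.29 (SE 0.12), Mmp7 at -0.34 (SE 0.17) and the claudin Cldn4 at -0.29 (SE 0.15). With an estimated correlation the adjusted p was 0.595 for both lists. The cholangiocyte call was lost without WT replicate 1 (adjusted p = 0.0996), WT replicate 3 (0.121) or HMGB2-KO replicate 1 (0.0922), within animals 38 to 41 (0.0584) and with camera on ranks. The cholangiocyte median lay between -0.22 and -0.15 with 1 liver left out, and at -0.21 within animals 38 to 41. The Kupffer median was 0.13 without HMGB2-KO replicate 3 (adjusted p = 0.0407). No single member of either passed, over all genes or adjusted over the list alone.

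The lists of liver genes that differ between the sexes were called in opposite directions at the preset correlation. The female-biased list fell, with 23 of 31 genes lower and a median of -0.15 (adjusted p = 0.00928, or 0.595 with an estimated correlation), led by Cyp2c40 and Cyp2c69, the sulfotransferase Sult3a1 at -0.53 (SE 0.18) and A1bg at -0.26 (SE 0.13). Cyp2c40 and Cyp2c69 passed when adjusted over the list alone, and 0 of its genes passed over all genes. The male-biased list rose, with 22 of 29 genes higher and a median of 0.12, or -0.00 with the values as deposited (adjusted p = 0.0108, or 0.697 with an estimated correlation), including Cyp4a12a at 0.39 (SE 0.12), Susd4 at 0.38 (SE 0.17), Ugt2b38 at 0.51 (SE 0.28, or 0.20 without HMGB2-KO replicate 2) and Hsd17b2 at 0.19 (SE 0.12). All 6 mice were male. Without WT replicate 2 neither passed, with medians of -0.15 for the female-biased and 0.05 for the male-biased list (adjusted p = 0.0668 and 0.344). Neither did without HMGB2-KO replicate 3, with medians of -0.09 and 0.05 (adjusted p = 0.152 and 0.143). The female-biased call was also lost without WT replicate 1, at -0.09 (adjusted p = 0.158).

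The lists of ribosomal and mitochondrial genes were called higher at the preset correlation. Of 53 cytosolic ribosomal protein genes 44 were higher, with a median of 0.10, or -0.02 with the values as deposited (adjusted p = 0.000853, or 0.697 with an estimated correlation), among them Rplp0 at 0.35 (SE 0.14), Rpl5 at 0.25 (SE 0.12), Rps7 at 0.27 (SE 0.13) and Rps15 at 0.27 (SE 0.16). Of 47 genes of oxidative phosphorylation 36 were higher, with a median of 0.09, or -0.03 with the values as deposited (adjusted p = 0.00281, or 0.697 with an estimated correlation), among them Cyc1 at 0.33 (SE 0.15), Uqcr10 at 0.23 (SE 0.14), Ndufa4 at 0.20 (SE 0.11) and Cox7c at 0.18 (SE 0.11). Without WT replicate 2, whose array stands apart, the medians were 0.05 and 0.01 (adjusted p = 0.105 and 0.316). The ribosomal call was also lost without HMGB2-KO replicate 1 (adjusted p = 0.0732).

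Inflammatory and metabolic hepatocyte lists made up the rest. The acute-phase list rose, with 28 of 32 genes higher and a median of 0.12 (adjusted p = 0.0108, or 0.595 with an estimated correlation), including the metalloreductase Steap4 at 0.61 (SE 0.28, or 0.27 without HMGB2-KO replicate 2), Saa4 at 0.39 (SE 0.22), Serpina3n at 0.21 (SE 0.14) and Itih4 at 0.21 (SE 0.17). Its median was 0.03 without HMGB2-KO replicate 3 (adjusted p = 0.326), and it did not pass without WT replicate 1 (0.13, adjusted p = 0.115), within animals 38 to 41 (adjusted p = 0.0584) or with quantile normalization either. The interferon list rose, with 30 of 37 genes higher and a median of 0.11, or -0.01 with the values as deposited (adjusted p = 0.0121, or 0.595 with an estimated correlation), although its member with the smallest p, Ifi27l2a, was at -0.47 (SE 0.20). Xaf1 (0.24, SE 0.13), Cxcl9 (0.28, SE 0.17) and Stat2 (0.29, SE 0.20) followed. The interferon call was lost without WT replicate 1 (adjusted p = 0.236), WT replicate 2 (0.0619), HMGB2-KO replicate 1 (0.0711) or HMGB2-KO replicate 3 (0.0840). Its median lay between 0.08 and 0.16 with 1 liver left out. The periportal list rose, with 17 of 22 genes higher and a median of 0.12 (adjusted p = 0.0121, or 0.595 with an estimated correlation), including Cyp2f2 at 0.25 (SE 0.13), Pigr at 0.25 (SE 0.13) and Ctsc at 0.29 (SE 0.16). Cdh1, at 1.89 (SE 1.18), owed its size to WT replicate 2 and was at 0.34 without it. The periportal call was lost without WT replicate 2 (adjusted p = 0.105), HMGB2-KO replicate 2 (0.0563) or HMGB2-KO replicate 3 (0.0547). Its median lay between 0.09 and 0.18 with 1 liver left out. The list of gluconeogenesis and glycogen genes rose, with 15 of 21 higher and a median of 0.14 (adjusted p = 0.0421, or 0.595 with an estimated correlation), including the insulin receptor substrate Irs2 at 0.46 (SE 0.16), glucose-6-phosphatase G6pc at 0.59 (SE 0.26), Pygl at 0.24 (SE 0.12) and the glucagon receptor Gcgr at 0.23 (SE 0.13), and its median was -0.01 without WT replicate 3 (adjusted p = 0.470). That call was also lost without WT replicate 1 (0.0577), HMGB2-KO replicate 1 (0.171) or HMGB2-KO replicate 2 (0.105), within animals 38 to 41 (0.330) and with camera on ranks. The median was 0.15 without WT replicate 1 and 0.11 within animals 38 to 41.

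Calls of lists depended on single livers. Without WT replicate 2, 8 lists passed, of which 4 were among the 10, namely the Kupffer, gluconeogenesis, acute-phase and cholangiocyte lists. Of the 10 lists, 5 passed without WT replicate 1, 8 without WT replicate 3, 6 without HMGB2-KO replicate 1, 8 without HMGB2-KO replicate 2 and 5 without HMGB2-KO replicate 3. The Kupffer list passed in each of these. Of the 26 lists that did not pass with all livers, 11 passed with 1 or another liver left out. With all livers, array weights and the replicate block called the cholesterol and pericentral lists lower, the replicate block, the animal term and camera on ranks called fatty acid oxidation higher, and camera on ranks called antigen presentation higher.

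**Figure D3:**
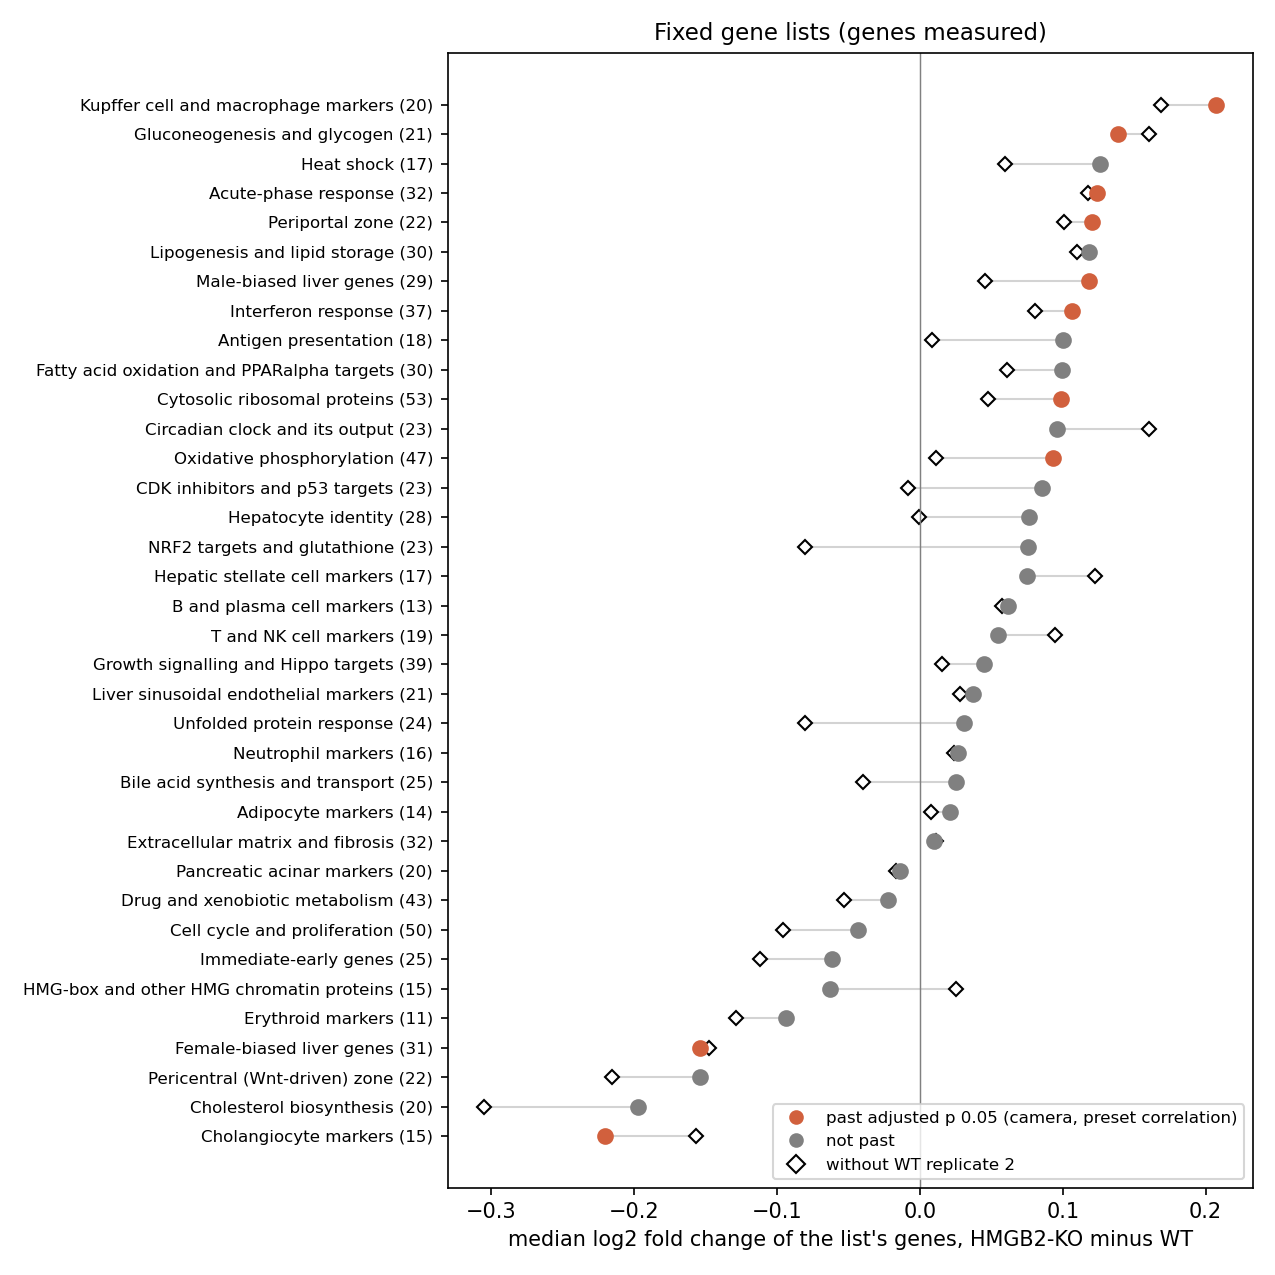
Median log2 fold change, HMGB2-KO minus WT, of the measured genes of each of the 36 lists (horizontal axis), with the number of genes in brackets, filled points for all 6 livers and open diamonds without WT replicate 2. The Kupffer list has the highest median at 0.21 and the cholangiocyte list the lowest at -0.22, and with the values as deposited every filled point lies 0.12 further left.

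The lists closest to the study's subject did not pass in the setting used throughout. Of 50 cell cycle genes 27 were lower, with a median of -0.04 (adjusted p = 0.461). Under quantile normalization, which the plan had called for, the list was called lower at -0.16 (adjusted p = 3.70e-05). Its median was -0.10 without WT replicate 2 (adjusted p = 0.0219) and 0.06 without WT replicate 3. Within it the spindle motor Kif11 was at -1.18 ± 0.22 in WT and -2.07 ± 0.24 in HMGB2-KO (SD, n = 3 each), a log2 fold change of -0.90 (SE 0.17), and it passed when adjusted over the list alone but not over all genes. The mitotic kinases Aurka (-0.50, SE 0.26) and Ttk (-0.33, SE 0.18) lay lower and Cdca3 higher (0.34, SE 0.17, or -0.57 with quantile normalization), none past the test. Growth signalling and Hippo target genes had 26 of 39 higher and a median of 0.05, or -0.07 with the values as deposited (adjusted p = 0.138), between 0.02 without WT replicate 2 and 0.09 without WT replicate 1, and called at 0.11 within animals 38 to 41 (adjusted p = 0.0293). In this list Wwtr1, which encodes the Hippo effector TAZ, was at 0.40 (SE 0.16), Egf at -0.46 (SE 0.20), Afp at -0.41 (SE 0.22) and Gpc3 at 0.27 (SE 0.15). The list of cyclin-dependent kinase inhibitors and p53 targets had a median of 0.09, or -0.03 with the values as deposited (14 of 23 higher, adjusted p = 0.307). Immediate-early genes had one of -0.06 (14 of 25 lower, adjusted p = 0.431), or -0.11 without WT replicate 2 (adjusted p = 0.0236) and 0.02 without HMGB2-KO replicate 3.

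Hepatocyte identity genes had 19 of 28 higher and a median of 0.08, or -0.04 with the values as deposited (adjusted p = 0.155). The list was called at 0.13 within animals 38 to 41 (adjusted p = 0.00579), and its median was -0.00 without WT replicate 2. Nr1i2 was at -0.35 (SE 0.19), Nr5a2 at 0.28 (SE 0.21) and Tdo2 at 0.22 (SE 0.19), and Apoa2, at 2.44 (SE 1.79) through the single array of WT replicate 2, was at -0.02 without it. Lipogenesis and lipid storage genes had 21 of 30 higher and a median of 0.12, or 0.00 with the values as deposited (adjusted p = 0.138, or 0.0248 as deposited and 0.0175 without HMGB2-KO replicate 2), and one of 0.06 without HMGB2-KO replicate 1 (0.553). The lipid droplet genes Cidea and Plin2 were at -0.54 (SE 0.16) and 0.39 (SE 0.18), the fatty acid transporter Cd36 at 0.37 (SE 0.15) and Pparg at 0.53 (SE 0.28). Cholesterol biosynthesis genes had 16 of 20 lower and a median of -0.20 (adjusted p = 0.138), with Rdh11 at -0.61 (SE 0.42), Nsdhl at -0.58 (SE 0.44), Pmvk at -0.42 (SE 0.43) and Cyp51 at -0.40 (SE 0.33). That list varied more between livers than any other, from -0.89 in HMGB2-KO replicate 2 to 0.61 in HMGB2-KO replicate 3, and its call turned on single livers. Its median was 0.19 without HMGB2-KO replicate 2 (called higher, adjusted p = 0.00265), -0.30 without WT replicate 2 (adjusted p = 0.0347), -0.62 without HMGB2-KO replicate 3 (adjusted p = 9.07e-08) and -0.61 within animals 38 to 41 (adjusted p = 3.29e-05).

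Other hepatocyte programmes did not pass in the setting used throughout. Fatty acid oxidation had a median of 0.10 (23 of 30 higher, adjusted p = 0.0565), antigen presentation 0.10 (15 of 18 higher, adjusted p = 0.0565), circadian clock genes 0.10 (17 of 23 higher, adjusted p = 0.205), NRF2 targets 0.08 (13 of 23 higher, adjusted p = 0.571) and the unfolded protein response 0.03 (13 of 24 higher, adjusted p = 0.571), and all of these medians are below 0 with the values as deposited. In that setting the fatty acid oxidation and clock lists were nevertheless called upward relative to all other genes (adjusted p = 0.00634 and 0.00881). Fatty acid oxidation was also called at 0.20 without WT replicate 1 (adjusted p = 0.00375) and at 0.24 without HMGB2-KO replicate 3 (3.92e-06), and was at -0.01 without HMGB2-KO replicate 2. Antigen presentation was called at 0.17 without WT replicate 3 (adjusted p = 0.000899), 0.14 without HMGB2-KO replicate 2 (0.0107) and 0.13 within animals 38 to 41 (0.00579), and was at 0.01 without WT replicate 2 (0.774). The unfolded protein response was called at 0.16 without WT replicate 1 (adjusted p = 0.0179) and was at -0.08 without WT replicate 2. Heat shock genes had a median of 0.13 (10 of 17 higher, adjusted p = 0.127), or 0.28 without HMGB2-KO replicate 1 (adjusted p = 0.00325) and -0.00 without HMGB2-KO replicate 3. The pericentral list had one of -0.15 (16 of 22 lower, adjusted p = 0.138), or -0.22 without WT replicate 2 (adjusted p = 0.00544) and -0.07 without WT replicate 1 or WT replicate 3 (0.713 and 0.389). Drug metabolism had one of -0.02 (23 of 43 lower, adjusted p = 0.367), or -0.15 without HMGB2-KO replicate 2 (adjusted p = 0.00169) and 0.08 without HMGB2-KO replicate 3. In that list Cyp2c40 passed, with all livers, when adjusted over the list alone. Median, mean and test differed in sign for bile acid genes (median 0.03, or -0.02 with quantile normalization and -0.09 with the values as deposited, mean -0.05, test upward, adjusted p = 0.959) and for the HMG proteins other than HMGB2 (median -0.06, or 0.00 with quantile normalization, mean -0.01, test upward, adjusted p = 0.903).

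Markers of other cells gave no further call with all livers. Medians were 0.04 for sinusoidal endothelial cells (13 of 21 higher, adjusted p = 0.142), 0.07 for stellate cells (12 of 17 higher, adjusted p = 0.0791, or 0.0458 at 0.13 without HMGB2-KO replicate 2 and 0.289 at 0.04 without HMGB2-KO replicate 1), 0.01 for extracellular matrix (18 of 32 higher, adjusted p = 0.575), 0.05 for T and NK cells (12 of 19 higher, adjusted p = 0.575) and 0.06 for B and plasma cells (10 of 13 higher, adjusted p = 0.515), all below 0 with the values as deposited. Neutrophil markers had a median of 0.03 with a mean of -0.02 and a downward test (adjusted p = 0.889), adipocyte markers one of 0.02 with a mean of 0.17 (adjusted p = 0.638), both below 0 with the values as deposited. Erythroid markers were at -0.09 (8 of 11 lower, adjusted p = 0.367) and pancreatic acinar markers at -0.01 (10 of 20 lower, adjusted p = 0.515).

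A knockout made in embryonic stem cells of another strain can carry that strain's sequence around the deleted gene, so the neighbours of Hmgb2 were tested as a set. The 40 measured genes nearest to Hmgb2 in gene order, 20 on each side, had a mean absolute moderated statistic of 0.932, against 0.858 for random windows (permutation p = 0.572). The lowest p among them was that of Adam29 at -0.72 (SE 0.25), followed by Gpm6a at 0.26 (SE 0.12). Windows of 10 or 40 genes on each side gave 1.14 and 0.911 (permutation p = 0.0980 and 0.584). Without WT replicate 2 the value for 20 genes was 1.09 and passed (permutation p = 0.0429), and without WT replicate 1 it was 0.796.

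Livers also differed along the labels' animal numbers. In the livers of animals 31 and 32, which are replicate 3 of each genotype, the clock output gene Dbp was at 0.09 and 0.11, against 3.64 to 5.55 in the livers of animals 38 to 41. The clock repressor Nr1d1 was at -1.57 and -1.52 against 2.88 to 3.27, and Rgs16 at -0.05 and 0.14 against 3.19 to 6.97. None of these differed between genotypes by more than its standard error, with Dbp at 0.45 (SE 1.61), Nr1d1 at -0.15 (SE 1.57) and Rgs16 at 0.97 (SE 1.90). Those standard errors hold the split by animal number, so they could hide a difference between genotypes. Within animals 38 to 41, with 2 livers per genotype, Hmgb2 was at -0.91, 0 genes passed the adjusted threshold in limma, 378 genes passed the looser one and 12 lists were called, 7 of them among the 10. Animals 31 and 32 are 1 liver per genotype and allow no test. With the animal numbers as a term in the fit, the counts were 0, 173 and 11, with all 10 lists kept.

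**Figure D4:**
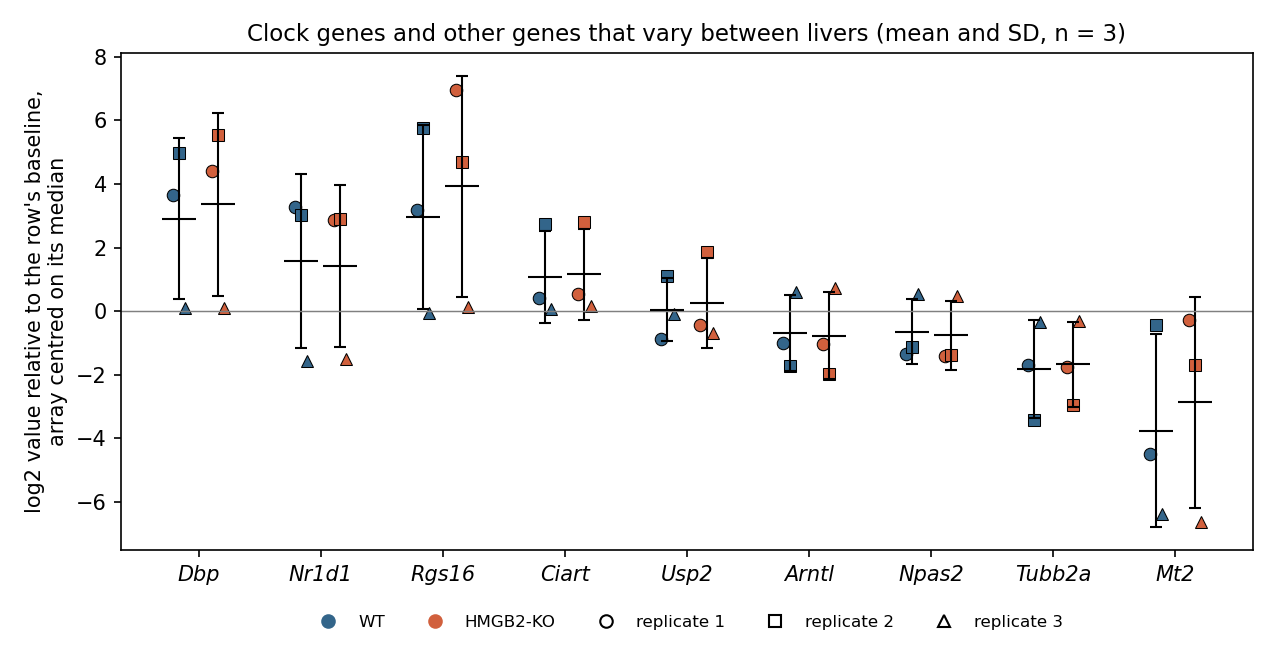
Log2 value relative to the row baseline after centring (vertical axis) of clock genes and other genes that varied between livers, with colour for genotype, symbol for replicate, and bars for the mean and SD (n = 3). Replicate 3 of both genotypes (animals 31 and 32) lies at 0.09 and 0.11 for Dbp and at 0.62 and 0.72 for Arntl, apart from the other 4 livers.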

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

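The explanations of the Cyp2c genes by shared probes or a single array, those of the Kupffer list and the counts over other splits of the livers were tested only after the results were seen. The test on the female-biased list was written before its result was seen. It keeps 29 of the 31 genes of a list called lower in the main setting. Its outcome was thus close to set by that call and is not separate support.

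Of the 7 measures of the arrays examined over the 6 livers, 6 put the array of WT replicate 2 far from all others. Its median over all rows was 0.26, that of olfactory receptor rows 0.51 and that of vomeronasal receptor rows 0.63. The SD of its values was 0.53, and it held 132 rows more than 2 log2 below, and 11 rows more than 2 log2 above, each of the other arrays. The bar for far is one that about 1 of 20 sets of values passes by chance, and these measures come from 1 array and are not independent.

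In HMGB2-KO livers Cyp2c40, Cyp2c67, Cyp2c68 and Cyp2c69 were lower by a mean log2 fold change of -1.12. The mean stayed at or below -0.92 whichever liver was left out, so no single array carried the difference in these values. The rule that named the 4 genes asks for no overlap of the groups and for large fold changes. That favours such an outcome, so it is no separate support. The female-biased list without its Cyp2c genes had a median of -0.13 (camera p = 0.0232 at the preset correlation and 0.325 with an estimated one), so a shift of female-biased genes as a set is one hypothesis for the pattern, and it rests on the preset correlation. Whether all 4 values come from 1 transcript read by the probes of several close copies, or from 4 separate changes, stays open. Probe sequences were not used here. The largest difference among the 4 fold changes, 0.41, is within 3 standard errors of a difference (0.29 each). That error treats the 4 genes as independent. They were read in the same livers, and the lowest correlation between any of them over the livers was 0.93. The error may thus be too large, and this comparison cannot decide the question.

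Kupffer and macrophage markers were higher in HMGB2-KO by a median of 0.21, or 0.13 without HMGB2-KO replicate 3 (adjusted p = 0.0407). By liver, the list's median in HMGB2-KO replicate 2 was 0.26, below WT replicates 2 (0.28) and 3 (0.38). HMGB2-KO replicates 1 (0.45) and 3 (0.55) lay above all WT livers. With an estimated correlation the list was not called (adjusted p = 0.595, and 0.0668 before adjustment). The array of WT replicate 2 is argued against as the whole cause, since the median without it was 0.17 (adjusted p = 0.00544, in a range over the camera alternatives of 2.86e-05 to 0.595). In fry, which asks instead whether the list differs from no change, the adjusted p was 0.792. A lower share of hepatocytes would raise every other cell type's markers alike. Medians were 0.04 for sinusoidal endothelial and 0.07 for stellate markers (-0.08 and -0.04 with the values as deposited), but -0.22 for cholangiocyte markers. The cholangiocyte call was lost with some single livers left out. The Kupffer median lay 0.43 above the cholangiocyte median (permutation p = 0.000220 over genes, which are not independent). These are the highest and lowest list medians, picked after the values were seen, so that p cannot decide the question. A lower share of hepatocytes thus stays open. More macrophages, or more of these transcripts per macrophage, stay open as hypotheses for the genotype and were not tested.

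Other splits of the same 6 livers into 3 and 3 number 10 with the real one, so the share with a result as large is never under 0.1. For genes past the adjusted threshold the real count was 0 and the highest other 2, and all 10 splits gave as many as the real one. The real count of genes at 1.5-fold and unadjusted p 0.05 was 148 and the highest other 399, with 6 of the 10 splits at 148 or more. Lists numbered 10 in the real split and up to 12 in the others, with 3 of the 10 splits at 10 or more. The 4 splits that keep the livers of animals 31 and 32 together gave 399, 348, 280 and 153 genes, and the other 5 gave 96 to 157. With the animal numbers as a term the count was 173.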

How the results depend on the processing

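The cause was not tested for any change listed here unless stated. No gene passed the adjusted threshold under any alternative run, and Hmgb2 stayed between -1.01 and -0.87 over the settings with all livers and between -0.96 and -0.80 with 1 liver left out. Among the named genes, 1179 values under alternatives kept their direction and 6 changed it. As no gene passed in any setting, none could change its side of the threshold. Among the lists, 536 stayed, 50 lost and 31 gained a call and 31 changed direction. Genes past 1.5-fold and unadjusted p 0.05 numbered 290 with the values as deposited, 63 with the per-gene test without moderation, 378 with animals 38 to 41 only (fewer livers), 32 at 2-fold and 158 to 331 with 1 liver left out. Lists called fell from 10 to 0 with an estimated correlation (smallest adjusted p 0.595) and with fry (0.360), and ranged from 7 to 13 with 1 liver left out. The statistic around Hmgb2 ranged from 0.796 to 1.09 with 1 liver left out.

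The direction of a gene's fold change or of a list's test changed as follows. With the values as deposited, Hmgb1 was at -0.023 and the test of the HMG list turned, at a median of -0.18. The medians of 20 lists changed sign there. With quantile normalization, Cdca3 was at -0.57 and bile acid genes at -0.023. With array weights, the unfolded protein response was at -0.039 and the test of bile acid genes turned, at a median of 0.022. With fry, the replicate block and the animal term the test of bile acid genes turned while their median stayed at 0.025, and with fry so did that of the HMG list at -0.063. With single-array drops set aside, Apoa2 was at -0.020. With animals 38 to 41 only, Nr5a2 was at -0.0083, the cell cycle list at 0.022, drug metabolism at 0.023 and the unfolded protein response at -0.10. With 1 liver left out, fold changes or tests turned within these ranges of medians: immediate-early -0.11 to 0.020, Apoa2 -0.020 to 3.71, bile acid -0.040 to 0.084, NRF2 -0.080 to 0.20, unfolded protein response -0.080 to 0.16, neutrophil -0.061 to 0.097, Hmgb3 -0.11 to 0.0039, cell cycle -0.096 to 0.062, B cell 0.013 to 0.086, HMG -0.087 to 0.033, extracellular matrix -0.057 to 0.035, cholesterol -0.62 to 0.19, fatty acid oxidation -0.0056 to 0.24 and drug metabolism -0.15 to 0.083. Medians alone crossed 0 for gluconeogenesis (-0.0071 to 0.16), circadian clock (-0.023 to 0.20), CDK inhibitors (-0.0085 to 0.14), adipocyte (-0.047 to 0.045), heat shock (-0.0011 to 0.28) and hepatocyte identity (-0.00061 to 0.12).

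Same-numbered livers deviated together with correlations over genes of 0.0363, 0.132 and 0.294, not all above 0.1, so by the rule set beforehand they were not taken as pairs, although 5 of the 6 correlate best with their own number. With the replicate block, 0 genes passed the adjusted threshold, 209 passed the looser one, 13 lists were called, all 10 of the main ones among them, and Hmgb2 stayed at -0.89. Filters on dim rows were planned and not run, because the values are differences from a row baseline and hold no level. For the same reason signal over background is unknown.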

Other observations

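The hypothesis on clock time has a test that was written before its result was seen. The other values in this part were looked up after the data were seen.

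Clock genes split the 6 livers by animal number in both genotypes. The activators Arntl and Npas2, which peak opposite to Dbp and Nr1d1 in liver, were higher in the livers of animals 31 and 32, at 0.62 and 0.72 for Arntl and 0.54 and 0.49 for Npas2, against -1.98 to -0.99 and -1.40 to -1.14 in animals 38 to 41. Another clock time at collection is a hypothesis for this split. It asks for the mean of Arntl, Npas2 and Clock to be higher in both livers than in any other, and the lower of the 2 livers lay 1.21 log2 above the highest of the other 4. The labels give no time of collection, so another state of the animals that resets the clock, such as feeding, may give the same pattern. Genotypes are balanced over this split, with 1 liver of each among animals 31 and 32.

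Among animals 38 to 41, same-numbered livers also matched in some clock genes. Ciart was at 0.42 and 0.55 in animals 38 and 39 and at 2.75 and 2.80 in animals 40 and 41. Usp2 was at -0.88 and -0.43 in the former and 1.10 and 1.88 in the latter, and Tubb2a at -1.70 and -1.74 against -3.43 and -2.96.

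Further genes with a large spread over the 6 livers were the metallothioneins Mt1 and Mt2, the fatty acid hydroxylase Cyp4a14 and the lipase inhibitor Angptl4. Mt2 was at -6.37 and -6.61 in animals 31 and 32 and between -4.48 and -0.28 in the others. Cyp4a14 was at -2.52 and -4.25 in those 2 livers and between -0.996 and 0.04 in the others. Angptl4 was at -1.76 and -0.75 against 1.42 to 2.29. None of the 3 differed between genotypes by more than its standard error, with Mt2 at 0.89 (SE 1.89), Cyp4a14 at -0.78 (SE 1.09) and Angptl4 at 0.70 (SE 1.05). The fit behind these standard errors has no term for the animal numbers. They hold the split itself and could hide a difference between genotypes.

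The cell cycle list lay below its row baselines in all 6 livers, with medians from -1.24 to -0.86, and the acute-phase list did too, with medians from -0.58 to -0.22. Sinusoidal endothelial markers lay above theirs, with medians from 0.41 to 0.63. The arrays behind the baseline are not given in the sources used here.

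Of the 14 Cyp2c genes measured, 12 were lower in HMGB2-KO, with a median of -0.35. The set was chosen after its values were seen. Of the 10 without those named by the rule, 8 were lower, among them Cyp2c54 at -0.56 (SE 0.13) and Cyp2c65 at -0.56 (SE 0.14), while Cyp2c55 was at 0.39 (SE 0.21). The median of these was -0.23. With the values as deposited every one of these is 0.12 lower.

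The 2634 rows with no gene name here were put through the same test. In limma 0 passed the adjusted threshold, where the smallest adjusted p was 0.129, 129 had an unadjusted p under 0.05, and 40 passed the looser threshold, 3 higher and 37 lower.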
